A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

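RNA of yap1d and WT yeast was extracted after 2 h in 200 mM hydroxyurea, labelled indirectly and hybridised to spotted yeast slides, per the labels. The values are log ratios of the 2 channels of a slide as deposited by the authors, with 6912 features in 8 columns, and no feature lacked a value. Log2 is assumed for these deposited values, because no label names the base. A natural logarithm remains possible and would change every fold but no test. Which channel is on top, the background correction and any normalization were not given in the sources used here. The values looked unnormalized: column medians ran from -0.28 to 0.04, slides of either orientation correlated at 0.760 to 0.858, and 24 features were at exactly 0 in all 4 fort columns. No column belonged to a sample outside the series.

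Gene names came from the array's annotation, updated through gene identifiers to the R64 yeast reference table. Of the features, 3344 had 1 gene symbol (3343 matched), 387 had several and were left unnamed, and 3181 were unnamed here. Features of a gene were averaged, which concerned 207 genes, leaving 6695 units (3127 genes and 3568 features without a single gene name). No genome build is named for the array, so no positions are given.

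Each column was centred on its median, the 2 scans of a slide were averaged, ratios were turned to yap1d over WT by the channels in the labels, and the 2 slides of a strain were averaged so that a channel effect cancels. The 2 strain backgrounds were the replicates. The design fixed before the data were examined said that columns of opposite orientation correlating above 0 would count as already turned and be kept. They did correlate above 0, and this rule was not followed. The reason is that slides of the same orientation correlated more (0.847 and 0.858) than slides of opposite orientation (0.760 to 0.810), and that TRX2 and TRR1 moved with the orientation. This was decided after the values were seen, and the count under the rule as written is in the closing section. The direction was then taken as likely from TRX2 and TRR1, since the feature meant to set it, that of YAP1, was not analysed here.

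The main test was an intercept fitted with lmFit and eBayes (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjusted p under 0.05. Its variance prior had infinite degrees of freedom against 1 residual degree, so its very small p-values rest on the assumption of 1 SD for all genes. Strain difference and channel effect were tested on the 4 slides with a channel term. The 24 gene lists with measured members, of 25 fixed before the data were examined, were tested with cameraPR (correlation preset to 0.01), and beside it with camera at an estimated correlation and fry on the 4 slides. The tests were checked on simulated data for the yap1d comparison over 6695 units, 200 of them changed. The main fit recovered 94.0% of changes of 0.5 and 100% of changes of 1 and 2 in log2, but 26 of its 222 calls were false, and 13 units were called when none was changed. The fit of 4 slides recovered 86.6% of changes of 0.5, with 9 false calls among 200 and none when no unit was changed. The simulated noise was shuffled over units, so it held no spread particular to a gene and no bias by place on the slide. The rates of false calls in the real data may therefore differ.

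The genes named were, by a rule fixed beforehand, the 15 largest falls and up to 10 largest rises that passed with the same sign on all 4 turned slides, read with the channel effect left in, up to 4 members of each list with the largest change, and up to 3 genes each for strain and channel. By that sign rule 26 falls and 6 rises could be named. Further list members are named to show members that did or did not pass. Alternatives varied the scan, centring, scaling, replicate unit, channel term, filters, variance prior, test, threshold and the slides used. Print block medians (48 blocks), loess, unturned columns, and scaling for lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9.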

Results

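Gene expression was compared between budding yeast (Saccharomyces cerevisiae) lacking YAP1 (yap1d) and wild type (WT), both grown in rich medium to an optical density of 0.5 and then kept in 200 mM hydroxyurea, an inhibitor of ribonucleotide reductase, for 2 h. Yap1 is a transcription factor that activates genes of the oxidative stress response. The comparison was made in 2 laboratory strain backgrounds, BY4741 (mating type a) and BY4742 (mating type alpha). Each background had 2 slides of a spotted array, on which yap1d and WT RNA were hybridised together with the channels exchanged, and each slide had 2 columns of values, titled fort and faible and treated as 2 scans, giving 8 columns in all. No culture without hydroxyurea was analysed here, so the values compare 2 genotypes under the drug and do not measure the response to it. The number of arrays limits the precision. Effects are given as mean log2 ratio of yap1d over WT ± SD over the 2 strain backgrounds (n = 2). The labels do not state that the 2 slides of a background came from separate cultures. P-values from fits on single slides may therefore measure technical spread, in part or wholly. The main p-values rest on the spread between the 2 backgrounds, which are different strains. Spread between cultures of the same background may not have been measured.

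The question of the main comparison was which genes depend on Yap1 in cells treated with hydroxyurea. The channel on top of the ratio and the base of its logarithm were not given in the sources used here. Base 2 was assumed, and the direction is only likely: it was set after the values were seen, so that TRX2 and TRR1, which Yap1 is known to activate, were lower in yap1d, and if it is wrong every sign below turns. GPX2, a glutathione peroxidase, fell by 2.29 ± 0.167, which is 4.90-fold, and YNL134C, a gene of poorly known function, fell by 2.14 ± 0.0133. The thioredoxin gene TRX2 (-1.57 ± 0.393), the copper-zinc superoxide dismutase gene SOD1 (-1.52 ± 0.0345) and YLR108C (-1.33 ± 0.192) fell as well. In the opposite direction, HEM13, an oxygen-dependent enzyme of haem synthesis, rose by 1.02 ± 0.183, which is 2.03-fold.

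Of 3127 genes tested, 66 passed an adjusted p of 0.05 with limma, 49 lower and 17 higher in yap1d. Among features without a single gene name, 51 of 3568 passed, 32 lower and 19 higher. Falls near 2-fold were measured for CYC1, which encodes iso-1-cytochrome c (-1.03 ± 0.0539), the sulfiredoxin gene SRX1 (-1.03 ± 0.326), the secreted glycoprotein gene YGP1 (-1.01 ± 0.155) and the thioredoxin reductase gene TRR1 (-0.998 ± 0.00265). The reductase gene GRE2 (-0.99 ± 0.162), the multidrug transporter gene PDR5 (-0.92 ± 0.188), the mitochondrial peroxiredoxin gene PRX1 (-0.79 ± 0.0433) and the iron-sulfur scaffold gene ISU2 (-0.69 ± 0.170, with its 2 features 0.37 apart) also fell. The peroxiredoxin gene AHP1 was lower, but the size of its fall is uncertain: its feature read exactly 0 in 2 of the 4 fort columns, as a saturated spot may, and its mean was -0.40 in the fort columns alone (adjusted p = 0.0677) and -1.79 in the faible columns alone. Besides HEM13, the genes that rose and had the same sign on all 4 turned slides with the channel effect left in were YDR061W (0.60 ± 0.0521), SIL1 (0.58 ± 0.0910), the zinc transporter gene ZRT1 (0.55 ± 0.0663), the protease B inhibitor gene PBI2 (0.51 ± 0.155) and AMN1 (0.41 ± 0.0840). GDH1, a glutamate dehydrogenase gene (0.81 ± 0.639), LAC1, GPD2, KAR2, YMR315W, TRK2, RIB3, PXP2 and TAD2 also rose, with the same sign on all 4 slides only once the channel effect of each gene was removed. Of these TRK2 (adjusted p = 0.126), RIB3 (0.108), PXP2 (0.0836) and TAD2 (0.198) did not pass the fit of the 4 slides and lost the call once print block medians were removed. Apart from KAR2, the genes from GDH1 on were named after their values were seen. YDR061W and SIL1 were at 0.39 and 0.37 once print block medians were removed, a setting added after the values were seen.

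Every mean in this fit had the same SE of 0.108, because limma set the spread of each gene to 1 common SD of 0.153. When the 4 slides were fitted separately with a term for the channel, 48 genes passed, 37 lower and 11 higher, and all 48 were among the 66. In that fit GPX2 had an adjusted p of 3.91e-07, YNL134C 1.31e-07, SOD1 2.34e-06, TRX2 2.93e-05 and HEM13 7.60e-05. The effects of the 2 backgrounds correlated across all units at r = 0.271 and across the 117 called units at r = 0.801, where genes are not independent replicates and the called units were chosen for their mean. The difference between backgrounds divided by 2, which holds no shared effect, was as large as the smallest called mean (0.36) in 13 genes. Without slide 19, or without slide 21, 3 genes passed (GPX2, YNL134C and SOD1), while 95 passed without slide 20 (58 lower, 37 higher) and 92 without slide 22 (49 lower, 43 higher). These are not 4 separate checks, because leaving out either slide of a pair left the same residual spread. Without slide 19 or 21 the variance prior had 3.47 degrees of freedom (common SD 0.146). It was infinite without slide 20 or 22 (common SD 0.187). The counts therefore do not show which slides hold the effects. The split of calls also moved with the normalization. It was 36 lower and 34 higher as deposited, 15 and 2 after quantile normalization, and 12 and 1 after a loess correction.

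**Figure D1:**
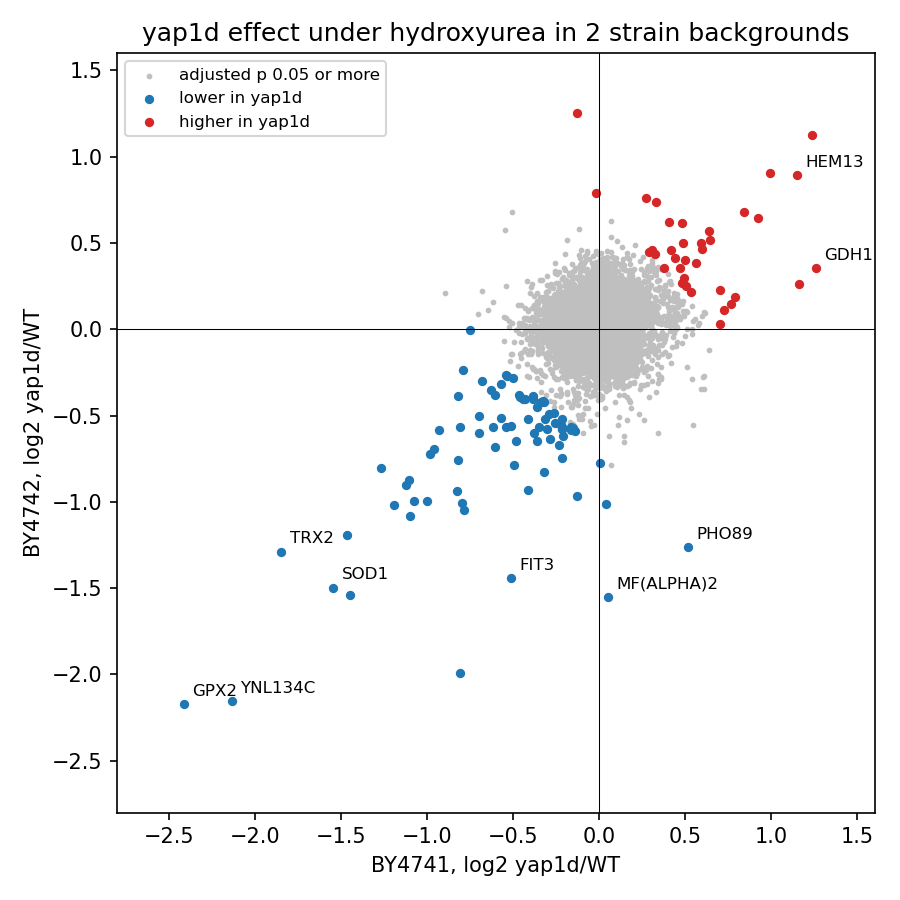
Each point is 1 gene or unnamed feature, with its log2 ratio of yap1d over WT in BY4741 on the x axis and in BY4742 on the y axis; coloured points are the 117 units with an adjusted p under 0.05. GPX2 and YNL134C lie at the lower left in both backgrounds, while PHO89 and MF(ALPHA)2 lie far from the diagonal.

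Genes known or reported as Yap1 targets were lower as a group by camera on the main fit with a preset correlation of 0.01 (adjusted p = 1.01e-104). Camera with an estimated correlation gave an adjusted p of 0.135. The estimate for this list was 0.00176, below the preset, so correlation does not account for the larger p of this list. Here and below, camera with an estimated correlation used the 4-slide fit, which has only 2 residual degrees of freedom. With fry on the 4 slides, used here to test for a shift of the members in 1 direction and not comparing with other genes, the adjusted p was 0.00564. Of the 24 measured members, 14 fell and none rose (15 fell adjusted over the list alone), and 21 had a mean below 0; the list mean was -0.69, with -0.71 in BY4741 and -0.66 in BY4742. The members that fell were GPX2, YNL134C, TRX2, SOD1, YLR108C, AHP1, SRX1, TRR1, GRE2, PRX1, ISU2, SNQ2, ECM4 and GTT2, of which GTT2 did not pass the fit of the 4 slides (adjusted p = 0.131). TRX2 and TRR1 set the direction, so their falls are no evidence of it. The other members did not set it, and those that passed all moved the same way as TRX2 and TRR1. That speaks for the direction taken, which stays only likely. The glutathione synthesis gene GSH1 (-0.31 ± 0.202) and the transporter genes FLR1 (-0.06 ± 0.132) and ATR1 (-0.10 ± 0.164) did not pass.

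**Figure D2:**
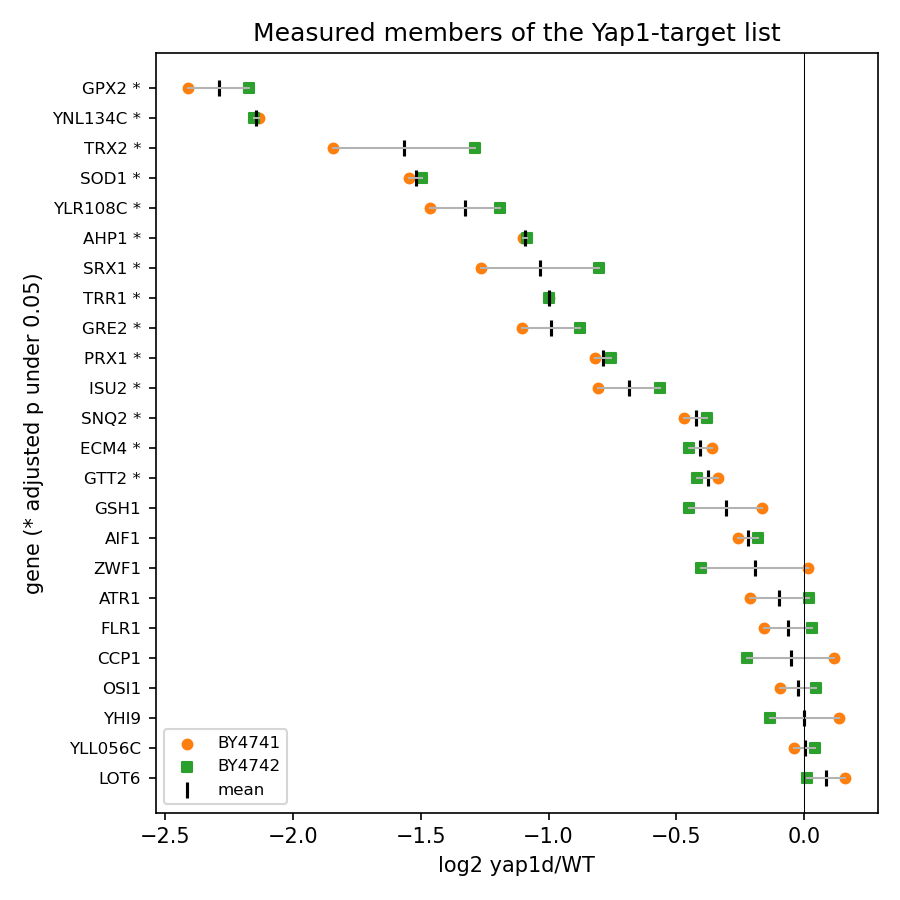
The log2 ratio of yap1d over WT on the x axis is shown for each of the 24 measured members of the Yap1-target list in BY4741 (circles) and BY4742 (squares), with their mean as a bar. The 14 starred genes passed an adjusted p of 0.05, from GPX2 at -2.29 to GTT2 at -0.38.

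The glutaredoxin gene GRX2, the mitochondrial manganese superoxide dismutase gene SOD2, the copper chaperone gene CCS1 and the flavohaemoglobin gene YHB1 also fell. In the thioredoxin and glutathione list, 9 of 22 measured members fell, 13 did not pass and none rose (10 fell adjusted over the list alone), with GRX2 at -0.49 ± 0.197; the list passed camera (adjusted p = 2.16e-42) but not with an estimated correlation (adjusted p = 0.195), and fry gave an adjusted p of 0.0233. Of 6 measured superoxide and catalase enzymes, 5 fell and none rose (5 adjusted over the list alone): SOD1, PRX1, SOD2 (-0.65 ± 0.0698), CCS1 (-0.55 ± 0.0186) and YHB1 (-0.42 ± 0.0274). GRX2 and YHB1 each read exactly 0 in 1 fort column, so the sizes of their falls are uncertain. CCP1, the cytochrome c peroxidase gene, did not pass (-0.05 ± 0.241). This list had a camera adjusted p of 3.91e-28, an adjusted p of 0.178 with an estimated correlation and 0.00564 with fry. Both lists share members with the Yap1-target list, so their tests are not independent of it.

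Among 16 measured multidrug transport genes, PDR5, SNQ2 (-0.42 ± 0.0628) and the polyamine transporter gene TPO1 (-0.42 ± 0.0186) fell and none rose, the same 3 falls adjusted over the list alone; camera gave an adjusted p of 0.000940, with 0.358 as the adjusted p at an estimated correlation and 0.0595 by fry. In the phosphate list, the acid phosphatase gene PHO5 (-0.58 ± 0.358) and the phosphate transporter gene PHO89 (-0.37 ± 1.26) fell among 5 measured members, also when adjusted over the list alone. Its camera adjusted p was 0.000448, and its adjusted p was 0.478 with an estimated correlation and 0.352 by fry. PHO89 did not pass the fit of the 4 slides (adjusted p = 0.778). It went opposite ways in the 2 backgrounds (0.52 in BY4741 and -1.26 in BY4742), its mean turned to 0.17 without slide 22, and the list mean was 0.03 in BY4741 and -0.53 in BY4742.

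Heat shock chaperones stood higher than other genes (list mean 0.12, with 0.05 in BY4741 and 0.19 in BY4742; camera adjusted p = 0.00428, adjusted p = 0.483 with an estimated correlation), while fry, which tests against no change, gave an adjusted p of 0.233. Of 17 measured members, KAR2, the chaperone of the endoplasmic reticulum, rose (0.44 ± 0.0309), and 2 rose adjusted over the list alone. HSP26 (0.31 ± 0.291) and SSE2 (0.25 ± 0.133) did not pass over all genes. Cytosolic ribosomal protein genes had small values in 1 direction: none of 49 passed alone or adjusted over the list alone, 47 lay below 0, and the list mean was -0.14, with -0.23 in BY4741 and -0.05 in BY4742. Their camera adjusted p was 2.34e-07, and the adjusted p was 0.478 with an estimated correlation and 0.239 by fry; paralogous ribosomal protein genes share sequence, so single values are uncertain.

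Genes of mating type had a list mean of -0.21, with -0.21 in BY4741 and -0.22 in BY4742 (camera adjusted p = 1.17e-05, adjusted p = 0.358 with an estimated correlation and 0.108 by fry). Of 11 measured members, the alpha-factor gene MF(ALPHA)2 (-0.75 ± 1.13) and the agglutinin gene AGA1 (-0.37 ± 0.0628) fell, 3 fell adjusted over the list alone, and neither passed the fit of the 4 slides, where MF(ALPHA)2 had an adjusted p of 0.438. MF(ALPHA)2 was at -1.55 in BY4742, the background that expresses alpha-factor, and at 0.05 in BY4741. The a-factor genes MFA1 and MFA2 were at -0.65 and -0.62 in BY4741 and at 0.11 and 0.16 in BY4742, and did not pass.

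**Figure D3:**
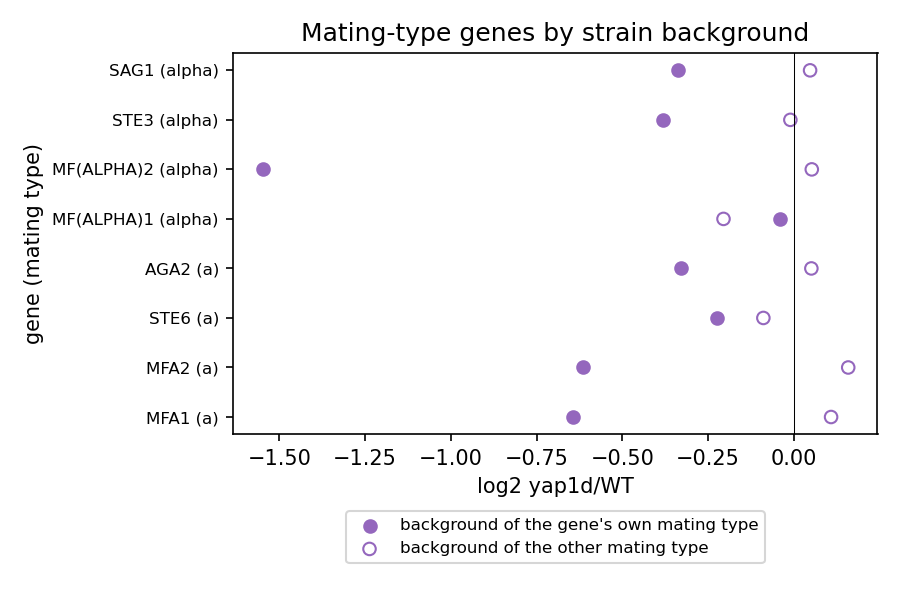
The log2 ratio of yap1d over WT on the x axis is shown for 8 genes specific to mating type a or alpha, with filled circles for the strain background of the gene's own mating type and open circles for the other. Own-background values lie lower in 7 of the 8 genes, MF(ALPHA)1 being the exception.

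The remaining 16 tested lists did not pass camera. Of 20 measured genes of the Aft1 iron regulon, FIT3, a cell wall mannoprotein that retains siderophore iron, fell by 0.98 ± 0.657 (-0.51 in BY4741 and -1.44 in BY4742) and ISU2 fell; the list had an adjusted p of 0.0819. Of 18 general stress genes under Msn2 and Msn4, YGP1, HSP12 (-0.49 ± 0.266) and GAC1 (-0.40 ± 0.259) fell (list adjusted p = 0.0923), and GAC1 did not pass the fit of the 4 slides (adjusted p = 0.102). In the respiratory chain, CYC1 and the NADH dehydrogenase gene NDE1 (-0.56 ± 0.116) fell among 28 measured genes (list adjusted p = 0.129), and of 17 sulphate and methionine genes the cystathionine beta-synthase gene CYS4 fell (-0.46 ± 0.151; list adjusted p = 0.894). None of 16 ribonucleotide reductase and DNA damage genes passed (list mean 0.05, adjusted p = 0.333), with RNR2 at 0.08 ± 0.201 and RNR4 at -0.02 ± 0.128; fry on the 4 slides gave this list an adjusted p of 0.0183 and the pentose phosphate and NADPH list 0.0140. No member passed among 4 AAD family genes, 10 pentose phosphate and NADPH genes, 23 proteasome genes, 32 ribosome biogenesis genes, 4 histone genes, 19 genes of G1 and S phase, 13 of G2 and M phase, 2 auxotrophic markers, 5 YAP family genes, 13 glycolysis genes or 10 cell wall integrity genes, and the list means of these lay between -0.08 and 0.07. Adjusted over each list alone, 1 AAD family gene fell, 1 gene of G2 and M phase fell and 1 rose, 1 cell wall integrity gene fell, 3 Aft1 genes fell and 1 rose, and 3 general stress genes fell and 2 rose. YAP1 itself and the genes beside it were not analysed here, because no feature carried their names alone, so the deletion was not checked in the values.

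The second comparison asked whether the effect of yap1d differed between BY4742 and BY4741. PHO89 had the largest difference, -1.78 ± 0.188 for BY4742 minus BY4741 (SE, 4 slides), with an adjusted p of 0.0575 in limma. GDH1, named after its values were seen, was at 1.26 in BY4741 and 0.35 in BY4742 (adjusted p = 0.0795). No unit passed, and 395 genes had an unadjusted p under 0.05. With the faible columns alone 73 genes passed and with the values as deposited 15 did, in fits with 1 residual degree of freedom.

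The third comparison concerned the channels and the 2 scans. RPS2 (1.14), YRF1-6 (1.12) and RTN1 (1.11) had the largest channel effects among named genes, given as the mean ratio over both orientations. With limma, 1963 genes had a channel effect, and its SD across units was 0.467, against 0.143 for the effect of yap1d. The fort and faible columns of a slide correlated across features at r = 0.953 on slide 19, 0.972 on slide 20, 0.966 on slide 21 and 0.972 on slide 22, with median absolute differences of 0.0850 to 0.120. Fort columns were more spread than faible ones by a factor of at least 1.32. MET17, which BY4741 lacks, stood at percentiles 12.1 and 9.57 of the ratios, not turned to yap1d over WT, on the BY4741 slides and 85.7 and 71.4 on the BY4742 slides. STE3, the receptor gene of alpha cells, stood at 6.32 and 7.48 against 47.5 and 92.6, and LYS2, which BY4742 lacks, at 77.7 and 73.5 against 33.3 and 37.7. The channels were exchanged between the slides of a background, so an effect of yap1d moves these percentiles in opposite directions on them. MFA1 was at 26.0 and 96.3 against 17.0 and 14.7, MFA2 at 35.6 and 98.1 against 41.6 and 26.2, and MF(ALPHA)2 at 29.6 and 25.7 against 0.224 and 100. MF(ALPHA)1, an alpha-factor gene, did not separate the backgrounds (4.12 and 22.4 against 4.08 and 16.3).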

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

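The strain test and the fit of 4 slides were planned. All other tests in this part, and the genes read in it, were chosen after the values were seen. Mating-type genes had lower values of yap1d over WT in the background of their own mating type, but in the strain test of the 4 slides none of the 8 genes passed, MF(ALPHA)2 being nearest (adjusted p = 0.267), so a difference between backgrounds is not established. Over the 8 genes the mean was -0.52 ± 0.461 (SD) in the own background and 0.01 ± 0.115 in the other, a difference of -0.53 with 7 of 8 genes lower in their own background (exact sign-flip test over genes, two-sided p = 0.0234; the genes prompted the test and are not independent replicates). A bias of these features that does not depend on expression cannot be decided on here. The mean of 0.0144 in the other background belongs to the pattern that prompted the test, and a difference between backgrounds is not established. A yap1d strain of the other mating type predicts that the other type's genes rise at least as far as the own genes fall. Their mean was 0.01 ± 0.115 (SD) in the other background, against -0.52 in the own one. That argues against it for these 8 genes, although the values belong to the same pattern (the other mean plus the own mean divided by 2 was -0.243). A lower pheromone response as a group stays open: the mean of 10 further response genes (-0.04 ± 0.0292, SE over genes) lay at percentile 11.4 of random lists (adjusted p = 0.303 over 4 lists). That list left out AGA1, FAR1 and TEC1, with which its mean was -0.12 ± 0.0453 (SE over genes). Those members were chosen by their values, so the mean with them is no evidence. In the fit of 4 slides FAR1 (adjusted p = 0.188) and TEC1 (adjusted p = 0.311) did not pass.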

How the results depend on the processing

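Filters on missing values removed no feature, so they could not change the count of 66 genes. That count stayed within 1.5 times under single scans, values as deposited, robust variances, features tested separately, adjusted p under 0.1 and the 4-slide fit. So it did, in settings added after seeing the data, with print block medians removed and with only genes of 1 symbol fitted. It was 18 with scaled columns, 17 with quantile normalization and 13 with loess (added after seeing the data), all among the 66; the variance prior then had 6.05, 5.34 and 4.50 degrees of freedom, against infinite, and the cause was not tested further. It was 10 at an absolute log2 of 1, by the stricter threshold, and 0 with the channel effect left in the 4-slide fit or with an ordinary statistic on 2 values. Leaving out a slide gave 3 to 95 genes. Unturned columns, the direction rule as fixed beforehand, gave 2127, which counts channel effects, since averaging both orientations unturned cancels the effect of yap1d. Settings with a similar count did not call all the same genes. As deposited, 53 of the 66 were among the 70 called, and with print block medians removed 58 were among 73. PHO89 ranged from -0.92 without slide 20 to 0.17 without slide 22, where its sign turned. The naming rule gave 34 called genes, which held all calls left with scaled columns, quantile normalization and loess; other genes named lost theirs there. Genes differing between backgrounds numbered 73 in faible columns and 15 as deposited, against 0; the cause was not tested. Gene lists passing numbered 0 with an estimated correlation and 5 with fry, both on the 4-slide fit with 2 residual degrees of freedom, against 8. The 5 were 3 of the 8 plus the DNA damage and pentose phosphate lists. Loess gave 7 lists, while the faible columns alone and print block medians removed each gave 10. Without slide 19, 21 or 22 some lists lost the call and others gained it. The fit with strain as a random block gave no estimate of its correlation, and YAP1 settings were not run. Signal over background was not given, so limits for dim genes are unknown.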

Other observations

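The main fit and the fit of 4 slides were planned. All other tests in this part, and the genes named first, were chosen after the values were seen. Other genes that fell in yap1d were the fatty acid elongase gene ELO1 (-0.59 ± 0.0362), the sterol desaturase gene ERG3 (-0.44 ± 0.195), the phospholipid methyltransferase gene CHO2 (-0.42 ± 0.144), the copper transporter gene CTR1 (-0.37 ± 0.0734), DRE2, which acts in cytosolic iron-sulfur assembly (-0.49 ± 0.160), and HAP4, an activator of respiratory genes (-0.49 ± 0.156). The ceramide synthase gene LAC1 (0.49 ± 0.0115), the glycerol-3-phosphate dehydrogenase gene GPD2 (0.47 ± 0.130) and YMR315W (0.43 ± 0.0203) rose. CTR1 did not pass the fit of 4 slides (adjusted p = 0.0546).

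The genes higher in yap1d were checked for place on the slide. The spread of the 36 units that rose over the 48 print blocks was not past 0.05 in unevenness against units shuffled over blocks (permutation test, 10000 shuffles, p = 0.151), so this test leaves a part played by spatial bias open. Blocks 10 and 11 held 4 risen units each, the most in any block, against 0.75 per block on average. Without block medians, TAD2, PYC2, SDS24, PXP2, TRK2 and RIB3, none of which passed the fit of 4 slides, lost the call, as their mean went from 0.38 ± 0.0197 to 0.19 ± 0.0237 (SD over genes). They lie in blocks 7, 10, 11 and 15. The block medians in BY4741 and BY4742 were 0.0275 and 0.21 in block 7 and 0.298 and 0.0513 in block 10. They were 0.139 and 0.174 in block 11 and 0.045 and 0.209 in block 15. Part of the rise of these genes was therefore shared with their whole blocks. SIL1 (0.58 to 0.37) and YDR061W (0.60 to 0.39), both in block 11, shrank but stayed past the threshold. The mean of all 17 genes that rose went from 0.51 ± 0.174 to 0.424 ± 0.251 (SD over genes), which argues against shifts of whole blocks as the whole cause for the 17 as a set.

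HEM13 rose while CYC1, HAP4 and NDE1 fell, and a hypothesis is that haem or oxygen signalling differed. Neither list decided it: 8 further genes repressed by Rox1 or induced by hypoxia had a mean of 0.06 ± 0.0606 (SE over genes), at percentile 91.8 of 10000 random lists matched on channel effect (adjusted p = 0.303), and 10 further haem-activated genes, which the hypothesis needs lower, had a mean of 0.01 ± 0.0257, at percentile 81.6 (adjusted p = 0.369) and so above the random median of -0.03. The first list left out HEM13 and the second the called members CYC1, HAP4, NDE1, SOD2 and YHB1. With them the list means were 0.17 ± 0.120 and -0.20 ± 0.0891 (SE over genes). Those members were chosen by their values, so the means with them are no evidence for the hypothesis. The means without them leave out the called members, so both parts of the hypothesis stay open.

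KAR2 and SIL1 both act in protein folding in the endoplasmic reticulum, and a hypothesis is that the unfolded protein response may be higher in yap1d. The mean of 7 further genes of that response was 0.09, at percentile 98.2 of random lists, which did not pass after adjustment over 4 lists (adjusted p = 0.142). It was 0.00321 in BY4741 and 0.17 in BY4742, and none of the 7 passed alone, so the hypothesis stays open. With KAR2 and SIL1 the list mean was 0.18 ± 0.0695 (SE over genes), but these members were chosen by their values, so that mean is no evidence. SIL1 lies in print block 11, and its rise was 0.37 without block medians.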
